A study of Chromochloris zofingiensis with 38 samples.

How the data were processed

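RNA was sequenced from wild-type cells of Chromochloris zofingiensis, a unicellular green alga, in a study of TOR inhibition and glucose addition. TOR (target of rapamycin) is a protein kinase that ties cell growth to nutrients. Per the labels, the samples carry 5 treatment names at 1 h and at 24 h. None marks no addition, AZD the TOR inhibitor and Glu the glucose. The labels do not spell out S or GA. GA has the initials of both treatments, and it is called here by its label. Each group held 4 libraries, except AZD at 1 h and GA at 24 h with 3 each, which made 38 libraries in 10 groups, 19 at each time. The title prefix of the samples changed together with the time, so levels at 1 h and 24 h were never tested against each other, and each difference was taken within 1 time. A response that differed between the times also differed between the prefixes.

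Per the labels' protocols, cell pellets were frozen, RNA was extracted and treated with DNase, libraries were made after poly(A) selection and sequenced as read pairs, and reads were quality-trimmed with BBDUK. The submitters' processing notes name Salmon and DESeq2 1.46.0, without their roles. The genome build, the annotation and the strand setting are not given in the sources used here. The deposited values are estimated counts per gene, which need not be whole and were not scaled for depth. The table held 12459 genes, of which 48 had no count in any library, and 0 columns belonged to other samples. Estimated counts were rounded to whole numbers before every test. Gene IDs were used as the table gives them. They come with no names or products, so 0 IDs could be matched to the pathway lists fixed in advance and no list was counted or tested. Reads of near-identical gene copies or overlapping genes can be divided between IDs by the estimation, which was not checked against a genome here.

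Library totals ran from 12414643 to 106150532 counts, an 8.55-fold range. A count of 3 per library was taken as the floor. Group means of named genes are printed also where single libraries lie below it, and the folds of these genes carry counting intervals. Counting intervals for genes with few counts are exact 95% Poisson intervals on the summed count of a group, scaled by the effective library sizes, and cover counting error only. Sequenced fragments are not independent molecules where they were amplified, and this error is not in the intervals. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 54 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom from 7.39 to 410 over genes with at least 10 counts), and none was counted as a duplicate.

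Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 12142 genes that held at least 99.998% of the counts of each library. Libraries were scaled with TMM factors, which set the middle of the expressed genes to no change, so rises and falls are relative to it. One quasi-likelihood model with a mean per group was fitted to the 38 libraries, with 28 residual degrees of freedom, a prior of 5.36 degrees of freedom and a common biological coefficient of variation of 0.20. Each p-value was adjusted over the 12142 genes by Benjamini-Hochberg, and a gene was called changed at an adjusted p under 0.05. The number that also changed at least 2-fold stands beside each count. Standard errors of log2 fold changes, printed as SE, were approximated from the fold change and the F statistic of its quasi-likelihood test. They are not exact standard errors and need not hold where folds are large or counts are few. For some named genes, leaving out a library moved the log2 fold change by more than this SE. Levels are CPM, the depth-normalised count unit of edgeR on TMM-scaled libraries, given as mean ± SD. Principal components and distances used log2 CPM with a prior count of 2.

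The pairwise comparisons at each time were AZD against None, AZD against S, S against None, Glu against None, GA against Glu and GA against AZD. A further contrast, GA minus Glu less AZD minus None, tested whether these differences were equal, and is called non-additive where it passed. The name describes joint action only if GA holds both treatments, which the labels do not state. Contrasts of the within-time differences tested whether the AZD or the Glu response changed between 1 h and 24 h. Fold changes were correlated across genes, which are not independent replicates, so no p-value was attached. For AZD and Glu, which share the None libraries, 20 simulated sets of unchanged groups and 6 splits of None into 2 sets of 2 were run. The genes named by ID were fixed by rule before the data were examined. In AZD against None, Glu against None and GA against Glu at each time, they were at most 2 with the largest rise and 2 with the largest fall among genes past the threshold, at a mean log2 CPM of at least 3, with every library of 1 group above every library of the other.

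The calling procedure was tested on simulated counts over 12142 genes, drawn from 1 mean per gene over all libraries and the effective library sizes of the real samples. For AZD against None at 1 h it recovered 72% of 100 genes changed 2-fold and 95% of 100 changed 4-fold, with 10 unchanged genes called. For AZD against None at 24 h these were 86% and 96%, with 9 unchanged genes called. For S against None at 1 h, simulated with no change, it called 0 genes. These simulations changed few genes, as many up as down. The real AZD against None comparisons called 55.7% of genes at 1 h and 73.4% at 24 h. Calling and scaling under changes that wide were not tested by the simulations. Alternatives fixed before the data were examined were DESeq2 1.42.0, the DESeq2 size factors in the edgeR test, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Scaling by library totals alone, leaving out S replicate 1 with Glu replicate 4 at 1 h, and TMM with another reference library, were added after seeing the data.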

Results

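Gene expression was measured by poly(A) RNA sequencing in 38 libraries of wild-type C. zofingiensis, taken 1 h or 24 h into treatment with nothing (None), the TOR inhibitor AZD, glucose (Glu) or the additions labelled S and GA. At 1 h the mean library total was 36844048 counts for None, 26550006 for S, 50500121 for Glu, 32290664 for AZD and 38260423 for GA. At 24 h the means were 21995422 for None, 23920055 for S, 57679874 for Glu, 25602222 for AZD and 46231260 for GA. Single libraries ran from 12414643 counts (None replicate 2 at 24 h) to 106150532 (Glu replicate 2 at 24 h). The 100 most abundant genes held 21.9% ± 0.969 of the counts in None at 1 h (SD, n = 4) and 31.6% ± 0.870 in GA at 1 h (n = 4).

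AZD, Glu and GA set the libraries apart from None, and more so at 24 h, while S lay near None at both times. At 1 h the group means of AZD and None lay 1.05 apart, as the root mean square of the log2 difference over 12142 genes, those of Glu and None 0.57 and those of S and None 0.34. At 24 h the same distances were 1.81 for AZD and None, 1.49 for Glu and None and 0.32 for S and None. GA lay nearer to AZD than to Glu at both times, at 0.67 against 1.06 at 1 h and 1.03 against 1.73 at 24 h. Single libraries lay 0.29 to 0.75 from the mean of the others of their group. The farthest were S replicate 1 at 1 h (0.75) and Glu replicate 4 at 1 h (0.70), against at most 0.58 for the other 36.

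**Figure D1:**
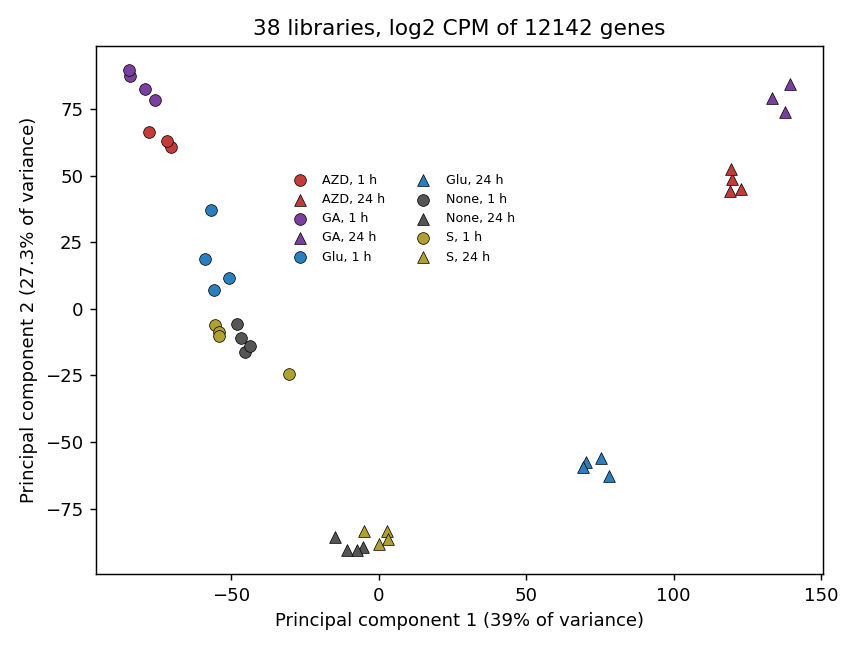
Each point is 1 of 38 libraries on the first and second principal components of log2 CPM over 12142 genes (horizontal axis 39% and vertical axis 27.3% of the variance), with colour for treatment and shape for time. AZD and GA libraries lie next to each other at each time, as do None and S libraries, and S replicate 1 at 1 h stands at -30.5 on the horizontal axis, away from the other S libraries at 1 h.

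S against None gave the lowest counts of the pairwise comparisons. At 1 h, 8 passed the test, of which 7 rose (4 at least 2-fold) and 1 fell (0), and at 24 h 116 passed, of which 49 rose (15 at least 2-fold) and 67 fell (5). Chance is not excluded for the count at 24 h, since in a fit of these 8 libraries alone 2 of 35 splits reached the 32 genes of the real one, and the other of them called 715. The gene that fell at 1 h was Cz13g07200, with a log2 fold change of -0.81 ± 0.17 (SE; adjusted p = 0.0475, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4), and it was chosen after its values were seen. With library totals alone, chosen after seeing the data, the rising share went from 87.5% to 100% of 3 genes at 1 h and from 42.2% to 74.5% of 51 genes at 24 h, and with the DESeq2 size factors 1 gene passed at 1 h, a rising one. DESeq2 called 67 genes at 1 h and 254 at 24 h, a fit of the groups compared only called 29 and 32, and without S replicate 1 and Glu replicate 4 at 1 h, left out after seeing the data, 156 passed at 1 h. In settings fixed in advance the rising share became 44.8% at 1 h in a fit of the groups compared only, and 51.9 to 83.3% at 24 h in 10 of 13. At an unadjusted p under 0.05 the test passed 1493 genes at 1 h and 1301 at 24 h. With no gene changed, a share of about 0.05 of the 12142 genes would pass, which is fewer than either number. The cause of this excess was not tested. Without S replicate 1 the count at 1 h was 77, and over the other libraries left out in turn it was 1 or 2. The count at 24 h was 176 without None replicate 1, 41 without None replicate 2, 20 without None replicate 3, 36 without None replicate 4, 63 without S replicate 2, 22 without S replicate 3 and 24 without S replicate 4.

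AZD against None set the samples with the TOR inhibitor beside those with no addition, and the labels do not say whether None received whatever the inhibitor was dissolved in. After 1 h, 6762 genes (55.7% of those tested) differed, of which 3660 rose and 3102 fell, and 1349 of the risen and 1458 of the fallen changed at least 2-fold. Among changed genes the median size of the log2 fold change was 0.88, and 69 genes fell at least 16-fold where 18 rose as much. The genes that rose took 61.9% ± 0.871 of the counts in AZD (SD, n = 3) and 41.6% ± 1.22 in None (n = 4), and those that fell took 6.14% ± 0.221 and 16.9% ± 0.632. Such shares, here and below, are of genes chosen by the same difference in the same libraries. Their direction follows from that choice and is no separate support. Scaling by library totals alone called 6668 genes and turned the split from 54.1% rising to 21.0% rising, with the median log2 difference of all genes at -0.37. Which direction held the majority is not settled, since the rising share was 45.5 to 47.0% in 6 of 12 other settings fixed in advance, and 46.5% with S replicate 3 at 1 h as the TMM reference library in place of None replicate 4 at 24 h, a reference chosen after seeing the data.

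Among the genes that met the naming rule, the largest rise at 1 h was in Cz13g08120, from 1.48 ± 0.566 CPM in None (n = 4) to 111 ± 27.5 CPM in AZD (n = 3), 75.7-fold with a log2 fold change of 6.24 ± 0.62 (SE). Cz07g19200 rose 65.1-fold, from 1.87 ± 0.497 to 123 ± 26.9 CPM (log2 6.02 ± 0.65). By the same rule Cz07g04070 showed the largest fall, from 36.7 ± 2.22 to 0.298 ± 0.0521 CPM, 118-fold lower (log2 -6.88 ± 0.30, 25 counts in AZD, 95% interval from summed counts 80.3 to 183). Cz06g06120 fell 83.1-fold, from 81.3 ± 3.71 to 1.02 ± 0.352 CPM (log2 -6.38 ± 0.24, 77 counts in AZD, 95% interval from summed counts 68.2 to 108). The adjusted p-values were 1.94e-10, 1.15e-09, 3.91e-19 and 1.69e-20 in that order (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, in each gene every AZD library lay on the same side of every None library. In GA at 1 h the same 4 genes stood at 146 ± 22.1, 66.3 ± 13.0, 0.344 ± 0.199 and 1.26 ± 0.263 CPM (n = 4), and in Glu at 5.79 ± 7.23, 3.84 ± 3.52, 36.8 ± 9.89 and 80.6 ± 13.8 CPM (n = 4). S replicate 1 and Glu replicate 4 held more of the risen pair than the other libraries of their groups, as the plot of these genes by library shows.

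By 24 h, 8909 genes (73.4%) differed between AZD and None, of which 4276 rose and 4633 fell. At least 2-fold changes numbered 2386 up and 2885 down, at least 4-fold 896 up and 1378 down, and at least 16-fold 136 up and 432 down. The median log2 size among changed genes was 1.20. The rising share of 48.0% became 51.1 to 52.0% in 10 of 13 other settings fixed in advance. The risen genes took 63.7% ± 1.07 of the counts in AZD (n = 4) and 23.7% ± 0.890 in None (n = 4), and the fallen genes 15.3% ± 0.338 and 54.1% ± 1.01. Counting genes with every library under 1 CPM in 1 group and every library at 10 CPM or more in the other, 141 were switched off in AZD and 17 switched on, against 12 off and 0 on at 1 h.

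Cz14g15120 rose 185-fold at 24 h, from 2.78 ± 0.754 CPM in None to 514 ± 66.1 CPM in AZD (log2 7.53 ± 0.45, n = 4 each), and Cz05g31250 rose 170-fold, from 6.57 ± 1 to 1120 ± 169 CPM (log2 7.41 ± 0.76). Cz03g21010 fell from 17400 ± 5790 to 9.21 ± 4.17 CPM, 1910-fold lower (log2 -10.90 ± 0.54). UNPLg00344 fell from 869 ± 283 to 0.0665 ± 0.0512 CPM (log2 -13.75 ± 0.62). The AZD libraries held 7 counts of UNPLg00344 in all, and the fold from these summed counts is 14700 with a 95% interval of 7120 to 36500. Adjusted p-values in this order were 1.27e-16, 1.19e-10, 9.96e-19 and 8.87e-20 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, every library of AZD lay on the same side of every None library. UNPLg00344 held 4.60 to 5.33% of the CPM of Cz03g21010 in 22 None, S and Glu libraries, 3.48 to 3.94% in the 7 AZD and GA libraries at 1 h, 3.08% in S replicate 1 and 2.75% in Glu replicate 4 at 1 h, and 0 to 1.62% in the 7 AZD and GA libraries at 24 h. At 24 h these ratios rest on 0 to 3.07 estimated counts of UNPLg00344 in each AZD library, around the floor, and 6.18 to 20.8 in each GA library. Whether reads are shared between the pair was not checked against a genome.

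**Figure D2:**
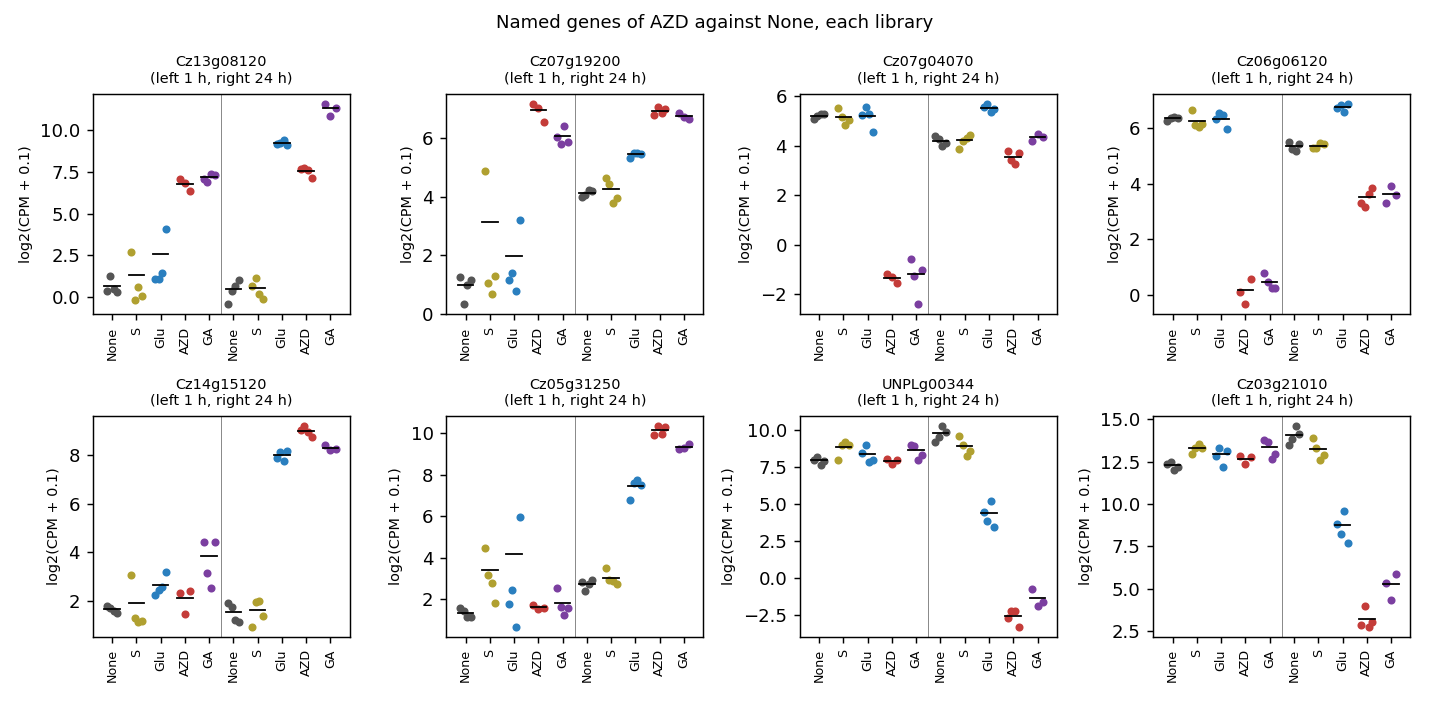
Each panel shows 1 named gene of AZD against None, with log2(CPM + 0.1) of every library on the vertical axis, treatments on the horizontal axis, 1 h left and 24 h right of the grey line, and a bar at the group mean. Cz13g08120 and Cz07g19200 are high and Cz07g04070 and Cz06g06120 low in AZD and GA at 1 h, while Cz14g15120, Cz05g31250, UNPLg00344 and Cz03g21010 part from None in Glu, AZD and GA at 24 h.

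AZD against S gave counts close to those against None. At 1 h 6549 genes differed (3447 rose, 3102 fell, with 1281 and 1479 at least 2-fold), and at 24 h 8823 differed (4124 rose, 4699 fell, with 2219 and 2827 at least 2-fold). With library totals alone the rising share at 1 h went from 52.6% to 27.0%. In other settings fixed in advance it was 45.0 to 45.8% in 3 of 12 at 1 h, and at 24 h it went from 46.7% to between 50.1 and 51.3% in 8 of 13.

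The AZD response at 24 h differed from that at 1 h for 62.0% of genes, in samples whose title prefix changed together with the time, so time and prefix cannot be told apart here. For 7534 genes the difference between AZD and None at 24 h was itself different from that at 1 h, at least 2-fold more positive for 2430 and more negative for 2726. Of these, 2901 were called only at 24 h, 1130 only at 1 h, 1787 at both times in 1 direction and 1627 in opposite directions, the last made up of 1037 that rose at 1 h and fell at 24 h and 590 that fell and then rose. Across all genes the log2 fold changes at 1 h and 24 h had r = 0.19 (Spearman's rho 0.25), with no library in common. Of the 3660 genes risen at 1 h, 1898 rose at 24 h (1289 if the lists were independent) and 1037 fell (1397 if independent). Of the 3102 fallen, 1697 fell again (1184 if independent) and 590 rose (1092 if independent). In the test of the difference, library totals alone moved the share with a more positive response at 24 h from 49.8% to 65.0%, and 17 of 20 other settings fixed in advance gave 50.4 to 58.3%.

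Glu against None asks what glucose addition changed. At 1 h 3781 genes (31.1%) differed, 2124 up and 1657 down, and 577 of the risen and 303 of the fallen changed at least 2-fold. The risen genes took 50.8% ± 3.86 of the counts in Glu (n = 4) and 35.1% ± 0.245 in None (n = 4). Library totals alone called 6586 genes and turned the split from 56.2% rising to 11% rising, with the median log2 difference of all genes at -0.45.

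Cz01g21060 rose 24.3-fold at 1 h, from 7.80 ± 1.89 CPM in None to 190 ± 103 CPM in Glu (log2 4.60 ± 0.42, n = 4 each). Cz11g03190 rose from 10.1 ± 1.64 to 132 ± 145 CPM (log2 3.70 ± 0.60), and without Glu replicate 4, which held 348 CPM, its log2 fold change was 2.56. Cz01g06080 fell 11.6-fold, from 70.3 ± 10.4 to 6.14 ± 2.55 CPM (log2 -3.54 ± 0.33), and Cz08g26170 fell 10.3-fold, from 99.3 ± 8.24 to 9.64 ± 2.25 CPM (log2 -3.37 ± 0.19). Adjusted p-values in this order were 1.89e-10, 9.52e-06, 1.97e-10 and 2.02e-15 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, every Glu library lay on the same side of every None library.

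At 24 h 8351 genes (68.8%) differed between Glu and None, 3979 up and 4372 down. At least 2-fold there were 1630 up and 2698 down, and at least 16-fold 46 up and 382 down. The risen genes took 70.2% ± 1.59 of the counts in Glu (n = 4) and 33.1% ± 1.18 in None (n = 4), and the fallen 11.9% ± 0.757 and 46.1% ± 1.44. By the same limits of 1 and 10 CPM, 50 genes were switched off in Glu and 4 switched on. Library totals alone moved the rising share from 47.6% to 34.9%, while 6 of 13 other settings fixed in advance gave 53.7 to 54.3%, so the majority among all changed genes is not settled.

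Cz13g05140 rose at 24 h from 0.131 ± 0.168 CPM in None to 159 ± 14.1 CPM in Glu (log2 10.63 ± 0.45, n = 4 each). None held 10 counts of Cz13g05140 in all, so its fold from summed counts is 1700 with a 95% interval of 922 to 3540, and without None replicate 2 the fitted log2 fold change was 11.81. Cz13g08120, which had the largest rise among the genes named in AZD at 1 h, rose 474-fold, from 1.30 ± 0.533 to 611 ± 59.8 CPM (log2 8.89 ± 0.68). Cz11g05100 fell 362-fold, from 196 ± 48.9 to 0.557 ± 0.118 CPM (log2 -8.50 ± 0.37), and Cz14g05220 fell 332-fold, from 163 ± 28.3 to 0.518 ± 0.254 CPM (log2 -8.38 ± 0.34). Adjusted p-values in this order were 7.83e-20, 1.92e-13, 9.86e-20 and 2.86e-20 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, every Glu library lay on the same side of every None library.

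For 6876 genes the Glu response at 24 h differed from that at 1 h, at least 2-fold more positive for 1487 and more negative for 2606, with the title prefix again changing with the time. Of these, 4405 were called only at 24 h, 665 only at 1 h, 834 at both times in 1 direction and 795 in opposite directions. Across genes the responses at the 2 times had r = 0.20 (rho 0.22). Of the 2124 genes risen at 1 h, 1271 rose at 24 h (696 if independent) and 346 fell (765 if independent), and of the 1657 fallen, 681 fell (597 if independent) and 449 rose (543 if independent). In the test of the difference, library totals alone moved the share with a more positive response at 24 h from 44.7% to 56.4%, and 10 of 21 other settings fixed in advance gave 52.8 to 53.7%.

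**Figure D3:**
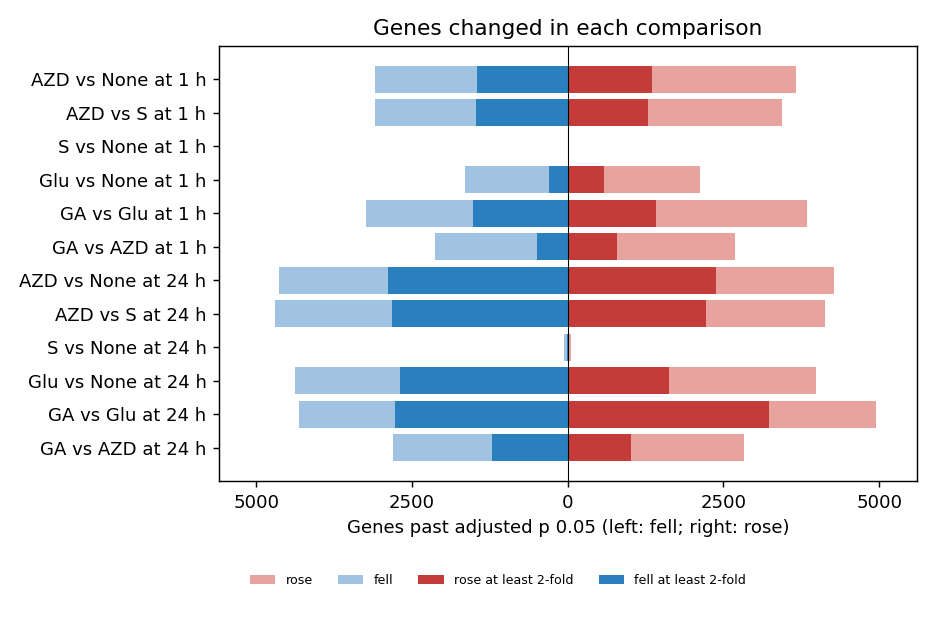
Bars count the genes past an adjusted p of 0.05 in each pairwise comparison, fallen genes to the left and risen genes to the right of 0 on the horizontal axis, with the darker part for changes of at least 2-fold. The bars for S against None hold 8 genes at 1 h and 116 at 24 h, and those of AZD against None and GA against Glu at 24 h are among the longest, at 8909 for AZD against None and 9265 for GA against Glu.

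GA against Glu set the samples labelled GA beside those labelled Glu. At 1 h 7083 genes (58.3%) differed, 3836 up and 3247 down, with 1424 and 1529 changed at least 2-fold, and at 24 h 9265 (76.3%) differed, 4948 up and 4317 down, with 3229 and 2774. At 1 h these changes followed those of AZD against None closely. Across genes r was 0.82 (rho 0.79), with no library in common, 2643 genes rose in both (1156 if independent), 2475 fell in both (830 if independent), 9 rose in AZD against None and fell in GA against Glu, and 27 did the reverse. At 24 h r was 0.62 (rho 0.66), 3255 rose in both (1743 if independent), 3137 fell in both (1647 if independent), 657 fell in AZD against None and rose in GA against Glu, and 265 did the reverse. With library totals alone the rising share at 1 h went from 54.2% to 20.9%, and it was 43.5 to 45.8% in 6 of 13 other settings fixed in advance. At 24 h it went from 53.4% to 49.6% in a fit of the groups compared only.

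Cz14g14210 rose 42.6-fold in GA against Glu at 1 h, from 43.4 ± 5.68 to 1850 ± 219 CPM (log2 5.41 ± 0.30, n = 4 each), and Cz07g24100 rose 40.4-fold, from 4.02 ± 1.13 to 163 ± 30.8 CPM (log2 5.34 ± 0.16). Cz10g07040 fell from 89.9 ± 8.38 to 0.802 ± 0.969 CPM (log2 -6.76 ± 0.41, and -7.86 without GA replicate 1). Its fold from summed counts is 110 (76 counts in GA, with 0 in replicates 2 and 4, 95% interval 87.5 to 139). Cz07g04070, which had the largest fall among the genes named in AZD against None at 1 h, fell 103-fold, from 36.8 ± 9.89 to 0.344 ± 0.199 CPM (log2 -6.68 ± 0.26, 33 counts in GA, 95% interval from summed counts 73.5 to 150). Adjusted p-values in this order were 7.51e-17, 3.32e-23, 7.42e-16 and 1.58e-20 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, every GA library lay on the same side of every Glu library. In AZD at 1 h the same 4 genes stood at 3050 ± 252, 300 ± 39.7, 2.44 ± 0.5 and 0.298 ± 0.0521 CPM (n = 3).

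At 24 h Cz10g05170 rose 132-fold in GA, from 2.22 ± 0.394 CPM in Glu (n = 4) to 294 ± 7.75 CPM in GA (n = 3; log2 7.04 ± 0.31), and Cz08g31100 rose 97.5-fold, from 0.647 ± 0.281 to 62.3 ± 8.59 CPM (log2 6.61 ± 0.24). Cz03g17150 fell from 915 ± 153 to 0.155 ± 0.103 CPM (log2 -12.57 ± 0.75), a fold of 6300 from summed counts (19 counts in GA, 95% interval 4030 to 10500). Cz14g15070 fell from 127 ± 6.44 to 0.0612 ± 0.0842 CPM (log2 -10.79 ± 0.59), a fold of 1850 from summed counts (9 counts in GA, 973 to 4040), and without GA replicate 4 its fitted log2 fold change was -12.95. Adjusted p-values in this order were 1.76e-19, 2.43e-21, 2.39e-16 and 2.93e-17 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the naming rule, every GA library lay on the same side of every Glu library.

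**Figure D4:**
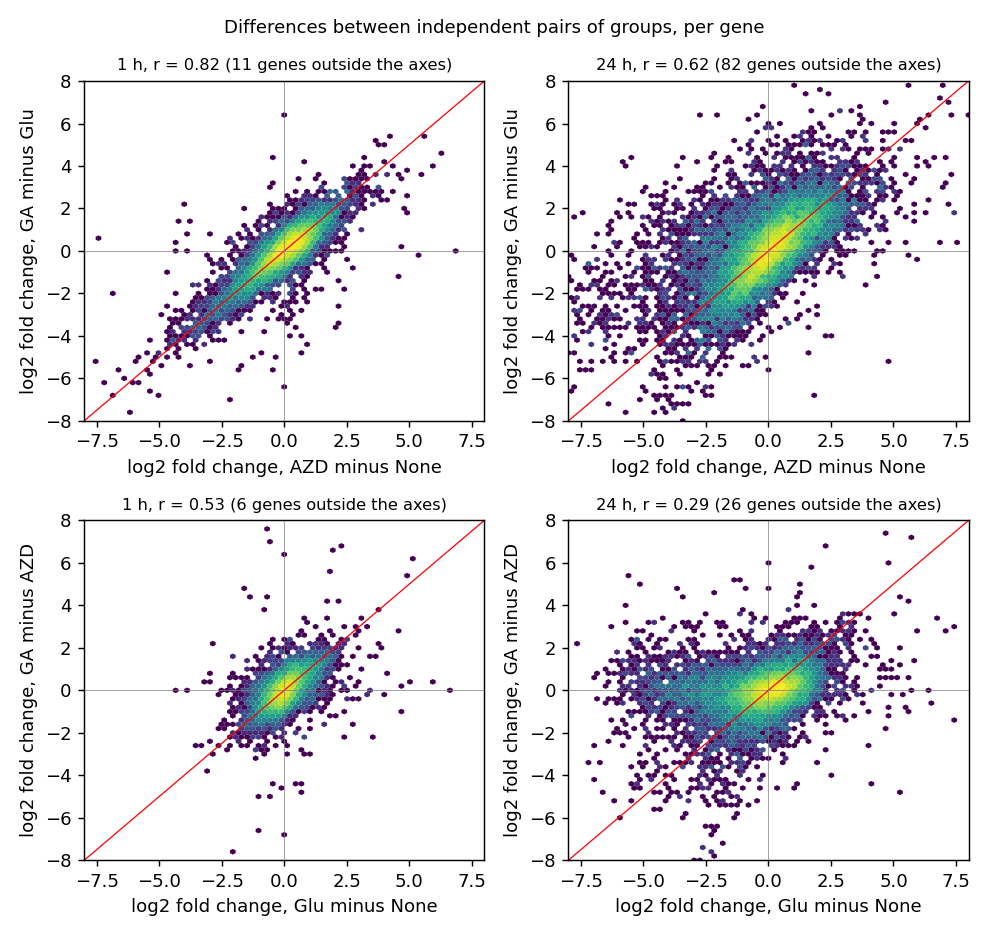
Density of 12142 genes by log2 fold change in 2 differences that share no library, AZD minus None against GA minus Glu (top) and Glu minus None against GA minus AZD (bottom), at 1 h (left) and 24 h (right), with the red line at equal change. Genes follow the line most closely in the top panel at 1 h (r = 0.82) and least in the bottom panel at 24 h (r = 0.29), where many genes that fell in Glu lie near 0 in GA against AZD.

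GA against AZD set the same samples beside those labelled AZD. At 1 h 4817 genes differed (2692 up, 2125 down, with 790 and 500 at least 2-fold), and at 24 h 5643 differed (2834 up, 2809 down), of which 1016 rose and 1223 fell at least 2-fold. Across genes these changes had r = 0.53 (rho 0.58) with those of Glu against None at 1 h and 0.29 (rho 0.32) at 24 h, with no library in common. At 1 h 1444 genes rose in both (471 if independent) and 907 fell in both (290 if independent). At 24 h 1594 rose in both (929 if independent) and 1565 fell in both (1011 if independent). Of the genes called in Glu against None, the GA against AZD change was a median 0.84 of the Glu change at 1 h and 0.23 at 24 h, and taken the other way, among genes called in GA against AZD, the Glu change was a median 0.54 of the GA change at both times. Library totals alone moved the rising share of GA against AZD from 55.9% to 14.2% at 1 h and from 50.2% to 27.8% at 24 h. Other settings fixed in advance gave 48.7 to 49.9% in 4 of 12 at 1 h and 47.0 to 49.9% in 9 of 12 at 24 h.

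Tested gene by gene, the difference between GA and Glu was not that between AZD and None for 547 genes at 1 h (133 at least 2-fold more positive in GA against Glu, 76 more negative) and 6424 (52.9%) at 24 h. At 24 h 3326 of these had the more positive difference in GA against Glu and 3098 the more negative, a split of 51.8% that became 41.2 to 43.6% in 11 of 20 settings fixed in advance, among them the DESeq2 size factors (41.6%). Larger differences were less even, at 2327 more positive and 1556 more negative from 2-fold, 1215 and 363 from 4-fold, and 389 and 65 from 16-fold. A gene near the floor in AZD or Glu alone has little room to fall further in GA, which by itself favours a more positive difference. At 24 h 432 genes fell at least 16-fold in AZD against None and 382 in Glu against None. How much of the imbalance comes from this limit was not tested. Among the 6424 genes, 3036 changed in 1 direction in both (1832 of them more in GA against Glu), 1360 were called only in GA against Glu, 1072 only in AZD against None and 922 in opposite directions. The same contrast also compares GA against AZD with Glu against None. Of the 3979 genes that rose in Glu at 24 h, 2227 had a lower difference between GA and AZD than between Glu and None and 190 had a higher one, while of the 4372 that fell in Glu 2669 had a higher one and 305 a lower one. The Glu and None libraries enter both the selection and the test, which by itself favours a smaller difference in GA against AZD. For genes that fell in Glu, the floor can favour the same. The count at 1 h was 955 with DESeq2, 217 in a fit of its 4 groups only, 297 without AZD replicate 3, 361 without GA replicate 4, 1297 without Glu replicate 3, 336 without None replicate 1, 326 without None replicate 2 and 998 without None replicate 3. Its share of more positive differences, 53.4%, became 45.1 to 49.6% in 11 of 20 settings fixed in advance.

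AZD and Glu, each against None, share the None libraries, which alone produce a correlation. Across genes r was 0.25 at 1 h and 0.50 at 24 h, against means of 0.45 and 0.51 in 20 simulations of unchanged groups. With the None libraries split into 2 sets of 2, r was 0.12 to 0.23 at 1 h and 0.44 to 0.50 at 24 h over 6 splits. The covariance was 0.168 at 1 h against 0.0355 simulated, a difference of 0.132, and 1.42 at 24 h against 0.0351 simulated, a difference of 1.39. At 24 h 1812 genes rose in both (1401 if independent), 2297 fell in both (1668 if independent), 1039 rose in AZD and fell in Glu, and 1224 did the reverse. At 1 h 1045 rose in both (640 if independent) and 730 fell in both (423 if independent). The simulations gave 0 genes called in both, but no gene was changed in them. They show what the shared None libraries give by noise alone. Neither that 0 nor the simulated r is therefore a measure of the overlap among genes that do change.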

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

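The tests of the libraries that lay apart were chosen after the values were seen. In groups of 4 libraries, 7 of 88 sets of values had 1 library far from the other 3 for the width of its group, where chance gives about 5%. S replicate 1 at 1 h stood at -30.5 on the first principal component, against -54.2 to -55.7 for the other S libraries. Glu replicate 4 at 1 h held 343 CPM of Cz01g21060 against 123 to 156 in the other Glu libraries, 348 CPM of Cz11g03190 against 47.1 to 71.4, 2.34 CPM of Cz01g06080 against 7.01 to 7.64, and 51.9 CPM of Cz14g14210 against 39.5 to 41.1. None replicate 2 at 1 h held 2.32 CPM of Cz13g08120 against 1.13 to 1.28. AZD replicate 2 at 24 h held 15.4 CPM of Cz03g21010 against 6.61 to 7.86.

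S replicate 1 and Glu replicate 4 at 1 h lay apart from their groups over all genes, and their deviations from the group means had r = 0.52 across 12142 genes. Depth is argued against, since after thinning every library to 12414513 counts they still lay 0.72 and 0.67 from the mean of their group's other libraries, where the highest of the other libraries was 0.54. A swap between them is argued against, since S replicate 1 lay farther from the Glu than from the S libraries by 0.16, and Glu replicate 4 farther from the S than from the Glu libraries by 0.16. RNA of another group mixed in is argued against as the whole cause, since 463 genes in S replicate 1 and 212 in Glu replicate 4 (at most 138 in the other 36 libraries) stood at least 2-fold below every other library of the group, which needs a foreign share of at least 50%, while genes at least 5 times higher in another group gave shares of at most 5.06% and 0.436% over 7 of the 9 other groups. In the 2 groups with too few such genes (None and Glu, or None and S, at 1 h), at least 97.4% and 96.2% of these low genes stood above the library in question in every library, which a mixture cannot give, and RNA from outside these groups or a difference in how the cultures were grown or handled stays open.

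Among the 24 entries of named genes, 17 had a response that itself differed by test between the times (and title prefixes) or between GA against Glu and AZD against None. They were chosen for the largest change in 1 comparison, which by itself favours a difference from another, and over all genes such a difference was called for 62.0% (AZD between times), 56.6% (Glu between times), 4.51% (non-additive at 1 h) and 52.9% (non-additive at 24 h). For AZD against None, Cz07g19200 rose by a log2 of 6.02 at 1 h and stood at 2.80 at 24 h, Cz07g04070 went from -6.88 to -0.64 and Cz06g06120 from -6.38 to -1.85. The genes named at 24 h stood near no change at 1 h, with Cz14g15120 at 0.47 against 7.53, Cz05g31250 at 0.29 against 7.41, UNPLg00344 at -0.03 against -13.75 and Cz03g21010 at 0.38 against -10.90. For Glu against None, Cz11g03190 went from 3.70 at 1 h to 0.33 at 24 h and Cz08g26170 from -3.37 to -1.82. Of those named at 24 h, Cz13g05140 stood at 2.33 at 1 h against 10.63, Cz13g08120 at 2.04 against 8.89, Cz11g05100 at -0.12 against -8.50 and Cz14g05220 at 0.11 against -8.38. At 24 h, Cz10g05170 rose by 7.04 in GA against Glu and 4.60 in AZD against None, Cz08g31100 by 6.61 and 1.78, and Cz03g17150 stood at -12.57 and -7.38 and Cz14g15070 at -10.79 and -3.51. The largest adjusted p of these differences was 0.000975, for Cz11g03190 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over 12142 genes for each contrast). Without Glu replicate 4 at 1 h the 2.04 of Cz13g08120 became 0.56 and its adjusted p went from 0.00356 to 0.392 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With each library of the 4 groups in a difference left out in turn, 15 or 16 for each gene, none of the other values set beside these 17 moved beyond 1.5-fold or crossed the threshold, and 0 of the differences were lost. In 5 of the 261 values the difference itself moved beyond 1.5-fold. It went from -3.37 to -2.23 for Cz11g03190 and from 6.85 to 8.33 for Cz13g08120 without Glu replicate 4 at 1 h, and at 24 h from 8.31 to 9.51 for Cz13g05140 without None replicate 2, from -13.71 to -13.07 for UNPLg00344 without AZD replicate 4 and from -7.29 to -9.44 for Cz14g15070 without GA replicate 4. The largest adjusted p among them was 0.00993, for Cz11g03190 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).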

How the results depend on the processing

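Library totals as the scaling, other TMM reference libraries, leaving out S replicate 1 with Glu replicate 4 at 1 h, and leaving libraries out of the correlations were chosen after seeing the data. Over the alternatives, 250 of 286 counts stayed within 1.5 times the reported count and 36 moved beyond it. The named genes kept their direction and their side of the threshold in 384 of 384 values. They were chosen for large changes with full separation of the groups, which by itself favours this, so it says little about other genes. No correlation changed sign. The majority of rising or falling genes was less stable. It turned in 113 of 232 values of the settings fixed in advance and for 15 of the 16 counts, Glu against None at 1 h being the exception (50.8 to 58.8% rising, but 11% with library totals), and the non-additive split at 1 h went from 53.4% to between 45.1 and 49.6% in 11 of 20. The reference library that TMM picks changed with 18 of 38 libraries left out, and with S replicate 3 or 4 at 1 h as the reference in all 38 libraries the majority turned in 25 of 32 values, so this choice alone can turn it. The counts that moved belong to S against None, to the non-additive response at 1 h and to Glu against None at 1 h. S against None at 1 h (8 genes) became 67 with DESeq2, 1 with its size factors, 29 in a fit of these groups only, 3 with library totals, 1 with either of these references, 1 without a filter, 156 without S replicate 1 and Glu replicate 4, and 1 to 77 with a library left out, the highest without S replicate 1. S against None at 24 h (116) became 254 with DESeq2, 32 with these groups only, 51 with library totals and 20 to 176 with a library left out, the lowest without None replicate 3 and the highest without None replicate 1. The non-additive count at 1 h (547) became 955 with DESeq2, 217 with its 4 groups only and 297 to 1297 with a library left out, the lowest without AZD replicate 3 and the highest without Glu replicate 3. Glu against None at 1 h (3781) became 6586 with library totals. Among genes of a mean log2 CPM of at least 3, the correlations of AZD against None with GA against Glu became 0.90 at 1 h and 0.66 at 24 h, and that of the AZD response at 1 h with 24 h became 0.24, with fewer and better measured genes. Apart from the smaller sets of genes or libraries, the cause was not tested. Equal replicate numbers did not pair the samples as a whole, since 19 of 72 same-numbered pairs had deviations correlated above 0.1 (mean r -0.032, against 0.011 for other pairs) and 5 of 38 libraries correlated best with their own number. Same-numbered None and AZD libraries at 1 h, picked out after their values were seen, had r of 0.133, 0.149 and 0.419. There None replicate 2 had a higher r, 0.176, with AZD replicate 1. With the replicate block, S against None at 24 h became 35, S against None at 1 h stayed at 8, and no other count moved beyond 1.5 times. Tests of gene lists with an estimated correlation were not run, since no ID could be matched to a list. Depth limits the genes under a floor of 3 counts per library, and folds of named genes resting on at most 77 summed counts in 1 group carry their intervals.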

Other observations

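The tests of hypotheses and the regroupings of libraries below were chosen after the results were seen. A set of genes changed in the same direction in all 4 of AZD against None and GA against Glu, at 1 h and 24 h, which share no library. It held 1312 risen genes, where independent lists would share 166, and 1261 fallen genes, where they would share 113. These numbers for independent lists, as elsewhere here, take every gene as equally easy to call. The agreement between pairs of these differences had also been seen already, so the excess is no separate support for it. At least 2-fold in each of the 4 differences, 395 rose and 388 fell. The matching set for Glu against None and GA against AZD at both times was smaller, with 591 risen genes (36.0 if independent) and 245 fallen (24.2 if independent), of which 127 and 49 changed at least 2-fold throughout.

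Response went with expression level in some comparisons, the level being taken from the S libraries of the same time, which enter none of these differences. In Glu against None at 1 h the median log2 fold change was -0.19 in the lowest of 4 equal sets of genes by level and 0.27 in the highest (Spearman's rho 0.35 across 12142 genes). In GA against Glu at 24 h it was 0.68 in the lowest and -0.23 in the highest set (rho -0.23). AZD against None gave rho 0.06 at 1 h and -0.08 at 24 h. Cz13g05140 stood at 1990 ± 22.4 CPM in None at 1 h and at 0.131 ± 0.168 CPM in None at 24 h (n = 4 each), a difference for which time and title prefix cannot be told apart.

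Genes with adjacent IDs responded somewhat alike, and the hypothesis is that neighbours in the ID order share part of their response. Over 11697 adjacent pairs and 6 comparisons, rho was 0.06 to 0.10 after the trend with level was removed (0.08 for AZD against None at 24 h), above the 0.032 that was the highest of 1000 shuffles in any comparison, with a permutation p of 0.001 each, the smallest that these shuffles give (0.001 after Benjamini-Hochberg adjustment). Reach past the immediate neighbour at a like strength is argued against, since IDs 2 places apart gave rho 0.012 for AZD against None at 24 h and 0.004 to 0.019 over the 6. These values are small but all above 0, so a weaker reach stays open. Reads spilling from an abundant to a scarce neighbour should raise rho in pairs of unequal level, and pairs at least 16-fold apart in level gave a rho lower by 0.06 (a difference of -0.06) than pairs within 4-fold, over a range of -0.15 to 0.00 in the 6 comparisons, which with 388 unequal pairs leaves spill open. The sources used here do not say how IDs were numbered, so position on the genome was not tested.

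TMM factors were low in GA at 1 h, 0.570 to 0.664 against 1.17 to 1.20 in None at 1 h. A few genes taking most of the counts are argued against as the cause, since the ratio of the group means was 0.51 with all genes tested, 0.56 with the 100 genes of the largest share removed and 0.64 with 500 removed. The treatment itself stays open and was not separated from a change in total RNA per cell, which these counts do not measure.

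Other splits of the same libraries into groups of the same sizes, tested on those libraries alone, argue against chance for most counts but cannot exclude it. The smallest share such a test can give is 0.0286 with 35 splits and 0.025 with 40, with no allowance for the number of counts tested. For S against None at 1 h the splits tested 29 genes, not the reported 8, which became 1 to 77 with a library left out. Of 35 splits each, only the real one, 1 split, reached its own count for AZD against None at 1 h (7069 genes, highest other 305), AZD against S at 1 h (5450, highest other 98), S against None at 1 h (29, highest other 1), Glu against None at 1 h (2972, highest other 209), GA against Glu at 1 h (5969, highest other 1) and GA against AZD at 1 h (4434, highest other 2). At 24 h the same held, with 0 genes in every other split, for AZD against None (9075), AZD against S (8792), Glu against None (8639), GA against Glu (9452) and GA against AZD (6146). Shuffled labels of a contrast of differences carry its pairwise differences, so its counts were first thinned at random to the lowest of the 4 rates of an additive fit. Of 40 splits of the thinned counts for each, 1 reached the real count, with 0 genes in every other split, for the non-additive response at 1 h (207) and at 24 h (6797), the AZD difference between times (7786) and the Glu difference between times (6781). Chance stays open for S against None at 24 h, where 2 of 35 splits reached the real 32 genes. The split of S and None at 24 h that called 715 genes set None replicates 1 and 2 with S replicates 3 and 4 against the remaining libraries, which points to a structure of these samples other than their treatment. Whether this structure is confined to S and None was not tested. At 24 h the deviations of S replicate 1 had r = 0.274 with AZD replicate 4 and -0.381 with AZD replicate 3. They had r = 0.256 with Glu replicate 3 and -0.199 with Glu replicate 4, and 0.26 with GA replicate 4 and -0.341 with GA replicate 3. These are the highest and lowest r in each group, picked after the values were seen. Deviations sum to 0 within a group, so r of both signs is forced there and does not decide the question.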
